A study of Homo sapiens with 21 samples.

How the data were processed

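Total RNA of 21 cultured cell samples had been hybridised to Illumina expression BeadChips, 1 array per sample. The deposited values are probe intensity values on a linear scale, exported with Illumina GenomeStudio per the submitters' processing notes (version not given in the sources used here). The deposited table shows no sign of background subtraction or of normalization between arrays: the lowest value was 66.3, array minima lay between 66.27 and 89.47, and array medians differed. Groups were taken from the sample labels, 3 arrays in each of 7 groups: KLE with shCTRL, hairpins 059 and 062 against MSH3, hairpins 543 and 603 against MSH6, and the control samples of HCT116 and MCF10A. The letters A, B and C of the KLE titles are taken as replicates 1, 2 and 3. HCT116 is spelled HCCT116 in the sample titles and HCT116 in the cell line field. All 21 columns of the table were used. The series design names further cell lines, which were not analysed here, and detection p-values were not used here.

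Values were transformed as log2(value + 16) and quantile-normalized over the 21 arrays. Of 47323 probes, 30113 carry 1 gene (20046 genes), 8 carry several and 17202 carry none. Probes with several genes or none were kept out of gene counts. Symbols were updated through their Entrez identifiers with a RefSeq gene table, which changed no symbol. Probes above the median of their array in at least 3 arrays of a fit were kept, and each gene was read by its probe with the highest mean. This left 14872 genes for the 15 KLE arrays and 14270 for the 9 control arrays. The brightest probe is not always the one that changes. For MSH3 both probes are reported because the bright one did not change, and its dim probe was added to the genes tested. A second probe of LUM gave smaller changes (mean 0.74 with the MSH3 hairpins and 0.52 with the MSH6 hairpins), and a second probe of CYP4X1 almost none (-0.07 and -0.10). The other probes of BTG3, KIT, GAGE4, PSMC4 and SULF2 had the same sign as the probe used.

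Groups were compared with limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), and every adjusted p for a gene comes from its two-sided moderated test with Benjamini-Hochberg adjustment over all genes of a fit, at a threshold of 0.05. The KLE groups shared 1 fit and the control groups of the lines another. A gene counts for a target when it passes with the same sign with both hairpins, since a change with 1 hairpin can be off-target, and its size is the mean of both hairpins with the SE of that contrast. MSH3 and MSH6 hairpins were compared as means and in all 4 pairs of hairpins. Shared changes were set against independent lists and against 100 simulations of unchanged groups with the same control arrays.

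The labels number the replicates, and whether these numbers pair the arrays was tested on residuals after group means. Among KLE arrays of different groups, residuals correlated across genes, which are not independent replicates, with a median r of 0.69 for replicate A (lowest 0.59), 0.53 for B (lowest 0.46) and 0.57 for C (lowest 0.39), each over 10 pairs of arrays. Between A and B the median was -0.60, between A and C -0.62 and between B and C 0.53. The residuals therefore set A apart from B and C in the KLE groups, which the labels do not state. They do not tell B from C, since B with C correlated as B with B. A fit with the replicate as a block is given beside the main one. In the control lines the median r of arrays with the same number was 0.048, -0.22 and -0.28, so these share only a number.

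The 23 gene lists were written from textbook knowledge before the data were examined, as were the main fit choices, the comparisons and the rule for named genes. They cover mismatch repair, homologous recombination and Fanconi genes, end joining, base and nucleotide excision repair, p53 targets, E2F targets, G2 and mitosis, interferon-stimulated genes, antigen presentation, NF-kB and cytokines, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, mesenchymal and TGF-beta genes, epithelial junctions, basal, colon and Mullerian epithelium, leukocytes, endothelium and the neighbours of the target loci. Lists with at least 5 tested members were tested with camera (two-sided, preset correlation 0.01, adjusted over the lists), again with a correlation estimated from the residuals, and with fry, which tests whether the genes of a list move, on balance, one way. Camera ranks a list against all other genes, so for lists with a median near 0 its direction can differ from that of the median, as for p53 targets with the MSH3 hairpins (median -0.01, camera up); no list past camera's threshold was of this kind.

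Named genes follow a fixed rule. For each target these are the 10 largest rises and the 10 largest falls that passed with both hairpins, ranked by the smaller change, or all where fewer passed, and MSH3 and MSH6 always. For MSH3 against MSH6 hairpins they are the 5 highest and 5 lowest in all 4 pairs, for each line the 8 genes with the largest smaller difference to the other lines, and for each list up to 4 members. Any mismatch repair member may be named. Genes outside the rule were named after their values were seen, and the text says so.

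The test was tried on simulated data with the spread of these arrays, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For 059 against shCTRL it recovered 62.7%, 79.1% and 97%, with 1 wrong call of 160, and for both hairpins together 59.7%, 77.6% and 95.5%, with 1 of 156 wrong. For MSH3 against MSH6 hairpins it recovered 82.1%, 89.6% and 98.5%, with 1 of 181 wrong, and for HCT116 against KLE 65.7%, 89.6% and 98.5%, with 9 of 178 wrong. With the block it recovered 79.1%, 100% and 100% for 059 (11 of 197 wrong), 73.1%, 97% and 100% for both hairpins (0 of 180 wrong) and 98.5%, 100% and 100% between targets (10 of 209 wrong). The other comparisons have the same group sizes and were not simulated separately. Camera found 1 list shifted by 0.3 and called 0 of 20 lists that were not shifted. The noise was drawn for each gene independently, so lists whose genes move together were not tried. The estimated correlation was 0.38 for the interferon-stimulated list. The simulated changes were set on the normalized log2 scale, so background compression is not part of these shares. In KLE each simulated change was the same with both MSH3 hairpins. Wrong calls between targets that come from effects of 1 hairpin are therefore not part of them either.

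Alternatives tried were median scaling, no normalization, cyclic loess, offsets of 1 and 50, quantile normalization within a fit, no filter or a filter at the 70th percentile, the mean of a gene's probes, all arrays in 1 fit, only the groups compared, a variance trend with a robust prior, array weights, a minimum fold of 1.5, the replicate block, the mean of both hairpins and leaving out each array in turn. Normexp background correction, a term for A against B and C, arrays B and C alone and the GAGE genes counted as 1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.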

Results

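Gene expression was measured on Illumina expression BeadChips in 21 samples of cultured human cells, with total RNA labelled in 1 colour and 1 array per sample. The arrays form 7 groups of 3. In 5 groups the cells are KLE, an endometrial carcinoma line, carrying a control hairpin RNA (shCTRL), hairpin 059 or 062 against MSH3, or hairpin 543 or 603 against MSH6. The other 2 groups are the control samples of HCT116, a colorectal carcinoma line deficient in mismatch repair, and of MCF10A, a non-tumorigenic breast epithelial line. MSH3 and MSH6 encode subunits of the complexes that recognise mispaired bases and small loops in DNA, and the series asks what defects in this repair do to the transcriptome. Array medians lay between 87.71 and 122.2 intensity units and single values between 66.3 and 24678. The lowest values were far from 0, so background remains in them and fold changes of dim genes are understated. The labels do not state that replicates came from separate cultures, so every p-value measures the spread between these samples only, and 3 arrays per group limit the precision.

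Among the 15 KLE arrays, the replicate letter separated samples more than the hairpin did. The arrays of replicate A lay apart from those of B and C on the first principal component, which carried 51.1% of the variance of the genes, against 13.2% on the second. In A, 3496 of 14872 genes were higher and 2519 lower than in B and C. The residual SD of the median gene was 0.127 on the log2 scale without a term for the letter and 0.0977 with one. Every KLE gene named below as passing without this term also passed with it, and counts from the fit with the letter as a block stand beside the main counts.

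**Figure D1:**
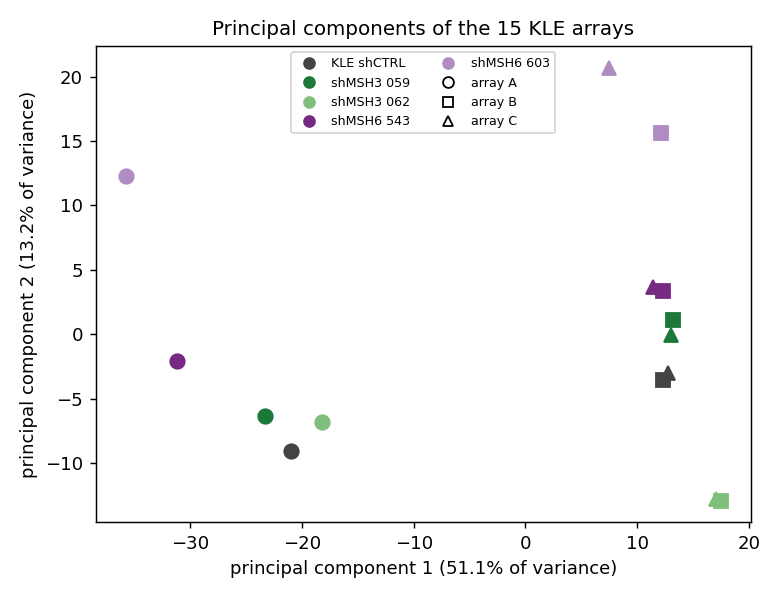
First principal component against the second for the 15 KLE arrays, in units of the component scores of log2 intensity, with points coloured by hairpin and marked by replicate letter. On the first component, with 51.1% of the variance, the A arrays lie between -35.8 and -18.2 and the B and C arrays between 7.49 and 17.5.

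The target transcripts were measured first. MSH6 fell to 23% of the shCTRL level with hairpin 543 (log2 change -2.12, SE 0.18, adjusted p = 6.2e-05, n = 3 arrays per group) and to 52.5% with hairpin 603 (log2 change -0.93, SE 0.18, adjusted p = 0.017). Its log2 level was 10.81 ± 0.29 (SD, n = 3) with shCTRL, 8.69 ± 0.3 with 543 and 9.88 ± 0.26 with 603. With the MSH3 hairpins the log2 change of MSH6 was 0.09 for 059 and -0.03 for 062. With normexp background correction, a choice made after seeing the data, the level with 543 was 19% and that with 603 was 50% of shCTRL. With median scaling and on the values as deposited neither fall passed (adjusted p = 0.1 and 0.31 for 543, 0.3 and 0.44 for 603), and a fit of only the groups compared lost the call for 603 (adjusted p = 0.11). The call for 603 was also lost on leaving out shCTRL replicate 1 (-0.77), shCTRL replicate 3 (-0.96), 603 replicate 2 (-0.83) or 603 replicate 3 (-0.88).

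MSH3 is read by a dim probe, ILMN_1719471, and a bright probe, ILMN_2077130, and they differed. On the dim probe MSH3 fell to 57.9% of shCTRL with hairpin 059 (log2 change -0.79, SE 0.13, adjusted p = 0.024) and lay at 63.7% with hairpin 062 (log2 change -0.65, SE 0.13, adjusted p = 0.062, and 0.026 with the letter as a block). Its log2 level was 8.72 ± 0.078 (SD, n = 3) with shCTRL, 7.94 ± 0.015 with 059 and 8.07 ± 0.28 with 062, against 7.28 ± 0.025 in HCT116. With the unadjusted limma p, the test fixed for a probe that is not the brightest of its gene, both falls passed (5e-05 and 0.00027). The mean of both hairpins on this probe was 60.8% of shCTRL (adjusted p = 0.017). On the bright probe the level was 97.5% with 059 (adjusted p = 1) and 87.5% with 062 (adjusted p = 0.9), so the fall of MSH3 rests on the dim probe alone. Which of the probes reads the MSH3 transcript was not checked.

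**Figure D2:**
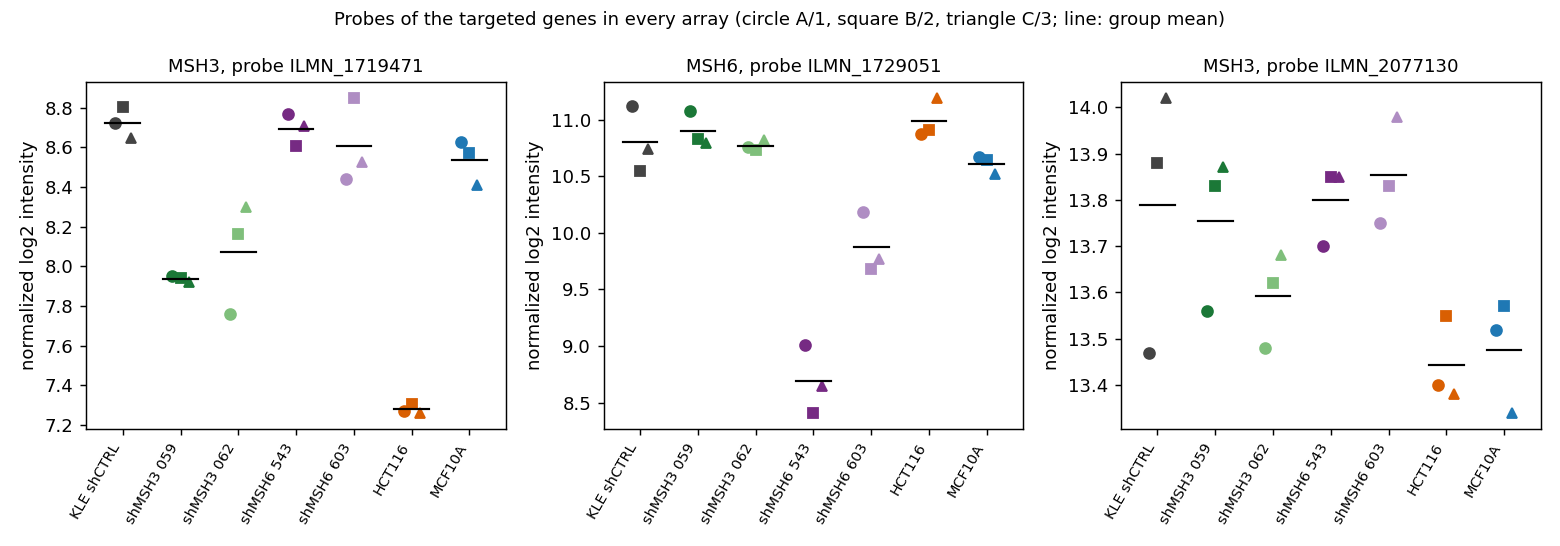
Log2 intensity of MSH6 and of both MSH3 probes on each array (points) with group means (lines) in the 7 groups. MSH6 is lowest with hairpin 543 (8.69 against 10.81 with shCTRL), the dim MSH3 probe is lower with 059 and 062 (7.94 and 8.07 against 8.72), and the bright MSH3 probe stays between 13.44 and 13.85 in all groups.

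Cells with the MSH3 hairpins were compared with shCTRL cells, although how far MSH3 itself fell is uncertain. In KLE cells with either MSH3 hairpin, the GAGE genes, cancer/testis antigens of the X chromosome that are normally silent outside the germ line, were far lower than with shCTRL. GAGE4 fell to 0.223 of the control level (mean log2 change -2.17, SE 0.14, adjusted p = 5.4e-06, n = 3 arrays per group), and GAGE12F and GAGE12G changed by -2.03 and -2.05 on the log2 scale. KISS1, which encodes the kisspeptin precursor, fell to 0.541 of control (log2 -0.89, SE 0.13, adjusted p = 0.013). Among the 4 rises, LUM, which encodes the proteoglycan lumican, was 2.51-fold higher (log2 1.33, SE 0.095, adjusted p = 1.3e-05), and COL3A1, a fibrillar collagen gene, 2.02-fold higher (log2 1.02, SE 0.12, adjusted p = 0.0018). All 4 rises and the fall of KISS1 passed under quantile normalization and not under median scaling or on the values as deposited, whereas GAGE4, GAGE12F and GAGE12G passed under all 3.

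In all, 21 genes passed with both MSH3 hairpins, 4 higher and 17 lower, and 51 passed with the letter as a block. The other 2 rises were ATG4B, a protease of autophagosome formation (1.56-fold, log2 0.64, SE 0.076), and C6orf120 (1.39-fold, log2 0.47, SE 0.054). GAGE12C, GAGE12B, GAGE12J, GAGE12H, GAGE2A and GAGE12D changed by -1.83, -1.81, -1.77, -1.69, -1.53 and -1.31. The GAGE transcripts are nearly identical, so a probe may read several of them, and the 11 GAGE genes that passed may stand for 1 change. The remaining falls, named after their values were seen, were smaller. The receptor tyrosine kinase gene KIT changed by -0.45 with 059 and -0.48 with 062, and the BMP-binding protein gene BMPER by -0.43 and -0.53. The keratin gene KRT16 changed by -0.76 and -0.82, the cytochrome P450 gene CYP4X1 by -0.79 and -0.47 and the cardiac troponin gene TNNI3 by -0.39 and -0.56. The last 2 were GAGE7 (-0.69 and -0.74) and GAGE12E (-0.38 and -0.34). KIT lay near the background, with a mean log2 level of 7.01 beside an array median of 6.92.

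Singly, hairpin 059 passed 59 genes, 20 higher and 39 lower (215 with the block), and hairpin 062 passed 51, 24 higher and 27 lower (193 with the block). Among the largest single-hairpin rises, also named after their values were seen, was DAAM1, an actin regulator, 1.84-fold higher with 059 (SE 0.12, adjusted p = 0.008). With 062 the cancer/testis gene VCX3A was 3.34-fold higher (log2 1.74, SE 0.16, adjusted p = 0.00017), and VCX3B and VCX were 3.24-fold and 3.19-fold higher.

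Of the gene lists fixed before the data were examined, 4 of 23 passed camera for the mean of the MSH3 hairpins, and none of these calls held with an estimated correlation. The interferon-stimulated list lay higher than other genes, with a median log2 change of 0.31 and 38 of 41 members positive, although on the values as deposited its median was just below 0, where that of all genes was -0.19 (camera adjusted p = 4.2e-12; adjusted p = 0.51 with an estimated correlation). In limma 0 of its members passed singly, 0 when adjusted over the list alone and 15 at an unadjusted p under 0.05, with the lowest p for IFIT3 (log2 0.80, SE 0.22, adjusted p = 0.26). The lists of E2F targets and of G2 and mitosis genes lay lower, with medians of -0.13 (camera adjusted p = 0.0089) and -0.11 (camera adjusted p = 0.016), and adjusted p = 0.51 for each with an estimated correlation. Without shCTRL replicate 1 the G2 and mitosis median was -0.023, and its call was lost. Of the mesenchymal list, LUM and COL3A1 passed with both hairpins and 3 members including TPM1, an actin-binding tropomyosin gene (log2 0.38, adjusted p = 0.028), passed in the mean contrast. There 6 were higher and 1 lower when adjusted over the list alone. The median of this list was 0.055 (camera adjusted p = 0.0012; adjusted p = 0.1 with an estimated correlation), 0.035 to 0.085 with 1 array left out, but -0.043 under median scaling and -0.15 on the values as deposited, where the medians of all genes were -0.082 and -0.19. In the basal epithelium list KRT16 fell with both hairpins and LAMB3, a laminin gene, was lower in the mean contrast (log2 -0.95, adjusted p = 0.024), while the list missed the threshold (camera adjusted p = 0.057). The mismatch repair list had a median of -0.014 (camera adjusted p = 0.56), and the remaining lists gave adjusted p of 0.07 or more, antigen presentation moving from 0.13 to 0.049 with the block (adjusted p = 0.6 with an estimated correlation).

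**Figure D3:**
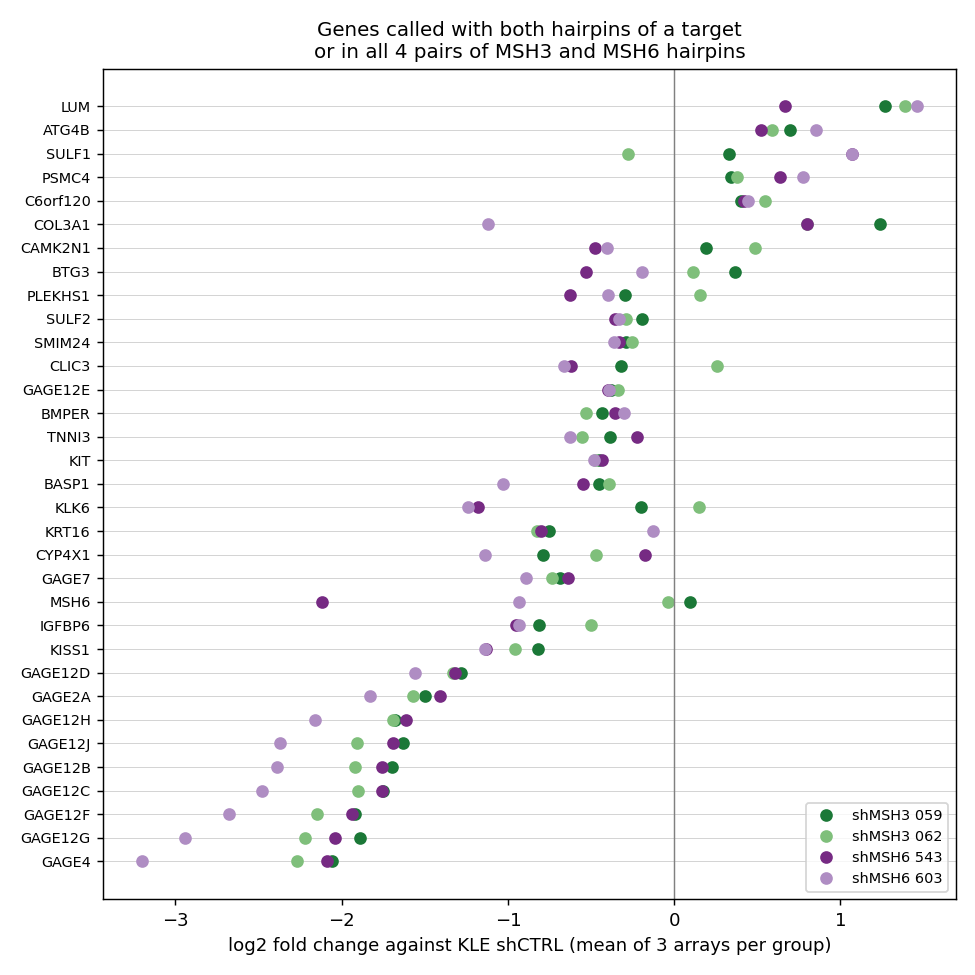
Log2 fold change against shCTRL of the genes that passed with both hairpins of a target or in all 4 pairs of MSH3 and MSH6 hairpins, with 1 point per hairpin (mean of 3 arrays against the mean of 3 shCTRL arrays). GAGE4 lies between -3.20 and -2.06 with all 4 hairpins, LUM between 0.67 and 1.46 (rises that did not pass under median scaling), and KLK6 is lower with 543 (-1.18) and 603 (-1.24) alone.

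The MSH6 hairpins were compared with shCTRL in the same way. Again GAGE genes were the largest falls: GAGE4 fell to 0.16 of control (mean log2 change -2.65, SE 0.14, adjusted p = 6e-07, n = 3 arrays per group), GAGE12G to 0.178 and GAGE12F to 0.201. With 603 these genes lay near the background (log2 6.79 to 6.95, beside an array median of 6.92), so the falls are understated. KLK6, a secreted serine protease gene of the kallikrein family, fell to 0.432 of control (log2 -1.21, SE 0.087, adjusted p = 1.2e-05). SULF1, which encodes an enzyme that removes sulfate from heparan sulfate outside the cell, was 2.1-fold higher (log2 1.07, SE 0.16, adjusted p = 0.007), and LUM 2.09-fold higher (log2 1.06, SE 0.095, adjusted p = 0.00015). PSMC4, an ATPase subunit of the proteasome, was 1.63-fold higher (log2 0.71, SE 0.097, adjusted p = 0.0045).

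With both MSH6 hairpins 27 genes passed, 5 higher and 22 lower, and 97 with the letter as a block. ATG4B (1.61-fold) and C6orf120 (1.35-fold) completed the rises, and none of the 5 rises, nor the fall of KLK6, passed under median scaling or on the values as deposited. On a second, dimmer LUM probe the mean change was 0.74 with the MSH3 hairpins and 0.52 with the MSH6 hairpins. GAGE12C, GAGE12B, GAGE12J, GAGE12H, GAGE2A and GAGE12D changed by -2.12, -2.08, -2.03, -1.88, -1.62 and -1.44. Named after their values were seen, the binding protein gene IGFBP6 changed by -0.95 with 543 and -0.93 with 603. The membrane protein gene BASP1 changed by -0.55 and -1.03, the chloride channel family gene CLIC3 by -0.62 and -0.66 and PLEKHS1 by -0.63 and -0.40. SMIM24 changed by -0.33 and -0.36, and SULF2, a relative of SULF1, by -0.35 and -0.33 at a mean log2 level of 6.96, near the background. MSH6 itself, KISS1 (-1.13 and -1.14), KIT, BMPER, GAGE7 and GAGE12E were the other falls.

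Hairpin 603 passed 323 genes, 108 higher and 215 lower (with the block 1017, 450 higher and 567 lower). Hairpin 543 passed 48, 18 higher and 30 lower (with the block 157, 82 higher and 75 lower). Among the largest changes of single hairpins, named after their values were seen, SPOCK2, a matrix proteoglycan gene, fell with 603 to 0.116 of control (log2 -3.11, SE 0.25, adjusted p = 4e-05). The interferon-induced genes IFI27 and MX1 changed with 603 by -3.03 and -2.46, and PLAT, which encodes tissue plasminogen activator, was 2.75-fold higher (SE 0.2, adjusted p = 0.0024). With 543, AGR2, a protein disulfide isomerase family gene of secretory epithelium, was 2.04-fold higher (log2 1.03, SE 0.075, adjusted p = 2.1e-05).

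For the mean of the MSH6 hairpins the interferon-stimulated list was the 1 list past camera's threshold. Its median was -0.27 with 34 members negative (camera adjusted p = 3.7e-11; adjusted p = 0.73 with an estimated correlation). IFI27 (log2 -2.19, SE 0.43, adjusted p = 0.035), MX1 (log2 -1.75, SE 0.3, adjusted p = 0.016) and IRF9, a transcription factor of the interferon response (log2 -0.98, SE 0.16, adjusted p = 0.011), were lower in this contrast. Adjusted over the list alone there were 11, and 10 passed with the letter as a block. With both hairpins separately limma passed 0 members, and the mean contrast had 1 higher and 19 lower at an unadjusted p under 0.05. In the mean contrast TPM1 was higher (log2 0.48, adjusted p = 0.0041), LAMB3 lower (log2 -1.12, adjusted p = 0.0047) and the glycolytic gene PFKP lower (log2 -0.40, adjusted p = 0.04). MSH6 was the mismatch repair member that passed, and that list had a median of 0.038 (camera adjusted p = 0.88). Ribosomal protein genes (camera adjusted p = 0.12) and oxidative phosphorylation genes (camera adjusted p = 0.15) missed the threshold, as did all other lists.

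Changes shared by both targets were asked for next. Of the genes that passed with both hairpins, 17 were common to MSH3 and MSH6, 3 higher (ATG4B, C6orf120 and LUM) and 14 lower (11 GAGE genes, KISS1, KIT and BMPER), and 0 passed in opposite directions. With median scaling 0 higher and 11 lower were common, and on the values as deposited 0 and 9. Independent lists of these sizes would share 0.0013 and 0.025 genes, and 100 simulations of unchanged groups against the same control arrays shared 0 in either direction. Neither shows how far shared controls raise the overlap of changed genes. Independent lists share no controls, and the simulated groups hold no changed genes. The fold changes of the targets correlated across genes with r = 0.495, where genes are not independent replicates, while simulated unchanged groups gave a mean of 0.666, because both targets share their 3 control arrays. Their covariance was 0.012 against a simulated mean of 0.00574. Of all genes 67.2% had the same sign for both targets, below the 73.2% of simulated unchanged groups. COL3A1, which rose with both MSH3 hairpins, differed from shCTRL by 0.80 with 543 and -1.12 with 603. With 1 control group, a gene that is unusual in the shCTRL cells appears as shared by all 4 hairpins.

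The MSH3 hairpins against the MSH6 hairpins compare the targets without the control arrays. Of 41 interferon-stimulated genes 19 were higher and none lower with the MSH3 hairpins, while camera's call for the list did not hold with an estimated correlation (adjusted p = 0.085). IFI27 was 5.45-fold higher (log2 2.45, SE 0.35, adjusted p = 0.0047, n = 2 hairpins of 3 arrays each per target). MX1, an antiviral GTPase gene, was 5.34-fold higher (log2 2.42, SE 0.24, adjusted p = 0.00054), IFI44L 3.35-fold and the ubiquitin-like modifier gene ISG15 3.12-fold (adjusted p = 0.0094). The SE and p-values of this contrast come from the spread within hairpin groups and leave out differences between hairpins of 1 target. Without the block none of the 19 passed in all 4 pairs of an MSH3 and an MSH6 hairpin. KLK6 was 2.27-fold higher (log2 1.18, SE 0.071, adjusted p = 1.5e-05) and CAMK2N1, an inhibitor of the calcium/calmodulin kinase CaMKII, 1.72-fold (log2 0.78, SE 0.068, adjusted p = 0.00023). Lower with the MSH3 hairpins were IGFBP5, an insulin-like growth factor binding protein gene (0.402-fold, SE 0.12, adjusted p = 0.00023), and SULF1 (0.484-fold, SE 0.13, adjusted p = 0.0021).

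In this contrast 309 genes passed, 168 higher and 141 lower with the MSH3 hairpins. With the letter as a block 1323 passed, 600 higher and 723 lower. In all 4 pairs of an MSH3 and an MSH6 hairpin 42 genes passed with the block, 22 higher and 20 lower with the MSH3 hairpins. With median scaling or on the values as deposited 0 passed there. Without the block 4 genes passed, all higher with the MSH3 hairpins. They were KLK6, MSH6 (2.94-fold, SE 0.13, adjusted p = 0.00023), CAMK2N1 and BTG3, an antiproliferative gene of the BTG/TOB family (1.52-fold, log2 0.60, SE 0.052, adjusted p = 0.00023). BTG3 held least well, with a smallest pair difference of 0.31. In limma without the block 0 genes were lower in all 4 pairs, and 85 were higher and 80 lower there at an unadjusted p under 0.05. Other large differences, named after their values were seen, were the antiviral genes OAS2 (2.9-fold) and IFITM1 (3-fold) and the prostaglandin D synthase gene PTGDS (2.93-fold, SE 0.28, adjusted p = 0.015). Lower with the MSH3 hairpins were LOXL4, of the lysyl oxidase family (log2 -1.12), BMP6, a bone morphogenetic protein gene (-0.86), HAS2, a hyaluronan synthase gene (-0.85), PLAT (-0.77) and WNT10A (-0.74). Against shCTRL, BMP6 and PLAT rose with 603 (1.09 and 1.46). BMP6 was also lower with 543 than with 603 (-0.895), so its difference between targets rests in part on 603.

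The 19 interferon-stimulated genes became 29 with the block and 32 adjusted over the list alone. Over all 41 the median difference was 0.59 and 39 were positive (camera adjusted p = 6.4e-36, and 0.085 with an estimated correlation). Fry, which does not rank the list against other genes, gave adjusted p = 0.0023. IRF9 was higher by 1.28 (SE 0.13, adjusted p = 0.00054) and IFI44L by 1.75 (SE 0.24, adjusted p = 0.0035). Against shCTRL of the same letter, the mean log2 change of the list on single arrays was 0.17 to 0.22 with 059, -0.084 in A and 0.68 and 0.66 in B and C with 062, -0.39 to -0.33 with 543 and -0.52 to -0.51 with 603.

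Some genes of DNA replication were lower with the MSH3 hairpins. In the E2F list 3 of 37 passed, all lower (6 with the block, 3 adjusted over the list alone). They were RRM2, a ribonucleotide reductase subunit (log2 -0.41, adjusted p = 0.032), the replicative helicase gene MCM3 (log2 -0.32, SE 0.066, adjusted p = 0.028) and the replication initiation gene MCM10 (log2 -0.26, adjusted p = 0.048). The list's median was -0.13 (camera adjusted p = 0.00047, and 0.39 with an estimated correlation). Against shCTRL of the same letter the list mean in A, B and C was 0.0212, -0.204 and -0.22 with 059 and -0.139, -0.074 and -0.107 with 062. It was 0.0962, -0.0626 and -0.0921 with 543 and 0.197, -0.0369 and -0.0154 with 603. In B and C, 062 thus lay close to 543. In the G2 and mitosis list, the cyclin gene CCNA2 was lower (log2 -0.46, SE 0.064, adjusted p = 0.0041), 1 of 35 members and 1 adjusted over the list alone (6 with the block), and the median was -0.13 (camera adjusted p = 0.0079; adjusted p = 0.47 with an estimated correlation). This call was lost without 543 replicate 1 (-0.080) or 603 replicate 2 (-0.064). Among base and nucleotide excision repair genes MGMT, the methylguanine methyltransferase gene, was higher (log2 0.58, SE 0.089, adjusted p = 0.0069) and the glycosylase gene NEIL3 lower (log2 -0.28, adjusted p = 0.044), with 2 higher and 3 lower adjusted over the list alone (3 higher and 4 lower with the block; camera adjusted p = 0.48). In the mismatch repair list MSH6 passed, with 1 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.47), and the block added 4 lower, among them EXO1 and RFC5, which both differed by -0.32.

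Antigen presentation genes lay higher with the MSH3 hairpins, with a median of 0.18 over 18 genes (camera adjusted p = 0.0034; adjusted p = 0.47 with an estimated correlation), although limma passed 0 of them, 3 at an unadjusted p under 0.05 and 3 with the block, and PSME1 and B2M differed by 0.35 and 0.34. Without 062 replicate 2 the median was 0.0995. Oxidative phosphorylation genes had a median of 0.15, but -0.0056 on arrays B and C alone (camera adjusted p = 0.017; adjusted p = 0.51 with an estimated correlation), and 1 of 32, UQCRC2, passed (log2 0.54), with 2 adjusted over the list alone and 3 with the block. The list's call was lost without 543 replicate 1 (0.054), 603 replicate 1 (0.064) or 062 replicate 2 (0.12). Ribosomal protein genes had a median of 0.13 over 43 genes (camera adjusted p = 0.0067; adjusted p = 0.47 with an estimated correlation), a call lost without 543 replicate 1 (0.040) or 603 replicate 1 (0.046). Against shCTRL of the same letter the list mean was -0.219 with 543 and -0.225 with 603 in A, and from -0.09 to 0.0138 in B and C. The Mullerian list had a median of 0.18 over 13 genes (camera adjusted p = 0.0079; adjusted p = 0.2 with an estimated correlation), with the folate receptor gene FOLR1 higher (log2 0.64, SE 0.13, adjusted p = 0.03), 2 adjusted over the list alone and 3 with the block. In the mesenchymal list COL3A1 (log2 1.18, SE 0.098, adjusted p = 0.00023), ACTA2 (0.87), DCN (0.77) and SPARC (0.41) were higher and THBS1 lower (-0.64) of 27, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.12). Against shCTRL, COL3A1 changed by 1.24 with 059, 0.797 with 062, 0.798 with 543 and -1.12 with 603, so 062 lay level with 543. ACTA2 differed by 1.70 between 543 and 603, more than between the targets. These 2 differences therefore do not hold for each MSH6 hairpin alike. PFKP of the glycolysis list was higher (log2 0.49, adjusted p = 0.0037; camera adjusted p = 0.73), as was ZCCHC9 of the neighbours of the target loci (log2 0.28, adjusted p = 0.024; camera adjusted p = 0.87). Camera gave adjusted p of 0.48 for homologous recombination and Fanconi genes, 0.14 for end joining, 0.73 for p53 targets, 0.87 for NF-kB and cytokines and for cholesterol synthesis, and 0.23 for the unfolded protein response. It gave 0.68 for the epithelial junction and basal epithelium lists, 0.95 for colon, 0.69 for leukocyte and 0.45 for endothelial genes.

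**Figure D4:**
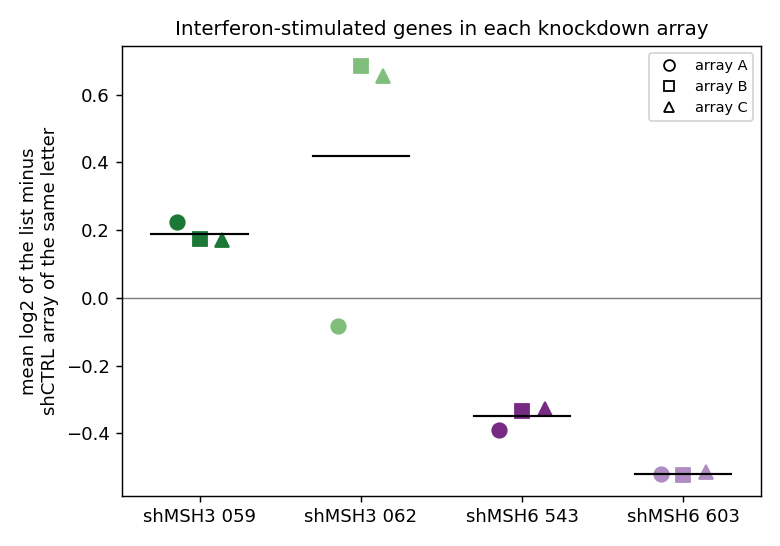
Mean log2 change of the 41 interferon-stimulated genes on each KLE array against the shCTRL array of the same replicate letter, with points marked by letter and a line for the mean of each hairpin. The MSH6 arrays lie between -0.52 and -0.33 and the MSH3 arrays between -0.084 and 0.68.

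Hairpins of 1 target were also compared with each other. VCX3A, an X-linked cancer/testis gene, was lower with 059, at 0.372 of its level with 062 (log2 -1.43, SE 0.16, adjusted p = 0.0031, n = 3 arrays per group), and VCX3B (-1.38), VCX (-1.40), VCX2 (-1.10), PAGE5 (-0.99) and MAGEA8 (-0.79) were lower too. TENM1, a teneurin adhesion receptor gene, was also lower with 059 (log2 -1.37, SE 0.11, adjusted p = 0.00051), and the microfibril gene MFAP5 was 2.1-fold higher (SE 0.17, adjusted p = 0.039). These genes were named after their values were seen. In all, 21 genes differed, 4 higher and 17 lower with 059. With the letter as a block 224 differed, 108 higher and 116 lower. The interferon list was lower with 059 (median -0.28, camera adjusted p = 0.0013; adjusted p = 0.6 with an estimated correlation; against this, 1 member higher and 0 lower adjusted over the list alone) and the NF-kB list higher (median 0.087, camera adjusted p = 0.002; adjusted p = 0.6 with an estimated correlation; 4 members higher adjusted over the list alone). The G2 and mitosis (camera adjusted p = 0.041), unfolded protein response (0.029, and 0.057 with the block) and ribosomal (0.029) lists were lower, each with adjusted p = 0.6 with an estimated correlation. In A alone 3 of these lists lay the other way, with list means against shCTRL of 0.224 with 059 and -0.084 with 062 for interferon, 0.111 and -0.057 for the unfolded protein response and 0.0122 and -0.0444 for ribosomal proteins, so their differences rest on B and C.

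Between the MSH6 hairpins, SPOCK2 was 7.98-fold higher with 543 than with 603 (SE 0.25 on the log2 scale, adjusted p = 0.00013, n = 3 arrays per group), COL3A1 3.79-fold (SE 0.14, adjusted p = 4.7e-05) and AGR2 2.95-fold (SE 0.075, adjusted p = 1.2e-06). The actin and tropomyosin genes ACTA2 and TPM2 were higher by 1.70 and 1.75 and the chaperone gene HSPA1A by 1.87. MSH6 was lower with 543 (0.439-fold, SE 0.18, adjusted p = 0.0057), as were the basement membrane collagen gene COL4A1 (0.433-fold), the cancer/testis gene MAGEC1 (log2 -1.07, SE 0.092, adjusted p = 0.00014), DICER1 (-0.80) and LUM (-0.79, adjusted p = 0.004). GAGE4 was higher with 543 by 1.11 (adjusted p = 0.0052), 1 of 7 GAGE genes that passed. With 603 it lay near the background (log2 6.82, beside an array median of 6.92), so this difference and the fall of GAGE4 with 603 are understated. Genes outside the target and the list members were named after their values were seen. In all, 176 genes differed, 126 higher and 50 lower with 543, and 542 with the block. The cholesterol synthesis list (median 0.23, camera adjusted p = 0.0048; adjusted p = 0.35 with an estimated correlation) and the glycolysis list (median 0.15, camera adjusted p = 0.0034; adjusted p = 0.31 with an estimated correlation) lay higher with 543. With the block, 3 more lists passed camera, G2 and mitosis (0.068 to 0.016), interferon (0.068 to 0.045) and antigen presentation (0.066 to 0.042), with adjusted p of 0.66, 0.86 and 0.71 with an estimated correlation.

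The control groups of the lines describe how the cells differ before any repair knockdown. KLE cells were set apart by FLG, which encodes the epidermal protein filaggrin, 107-fold above the nearer of the other lines (log2 6.75, adjusted p = 2.2e-11, n = 3 arrays per line), SPOCK2 (53.6-fold), BEX1 (51-fold), SPON1 (39.1-fold), the branched-chain aminotransferase gene BCAT1 (34.1-fold), the ubiquitin hydrolase gene UCHL1 (32.8-fold), the kidney and Mullerian cadherin gene CDH6 (27.3-fold) and LGALS14 (26.4-fold). MCF10A cells were set apart by the aldo-keto reductase gene AKR1C2 (73.9-fold, log2 6.21, adjusted p = 1.4e-11), KYNU, of tryptophan breakdown (58.2-fold), AKR1C4 (47.6-fold), AKR1C3 (44.9-fold), the calprotectin genes S100A8 (45.8-fold) and S100A9 (41-fold), TGFBI (39.8-fold) and CLCA2 (28.2-fold). AKR1C2, AKR1C3 and AKR1C4 are close paralogs whose probes may cross-hybridise. HCT116 cells were set apart by GTSF1, of the germ line piRNA pathway (25.3-fold, log2 4.66, adjusted p = 1.4e-10), the homeobox gene HOXB8 (18.7-fold), the cancer/testis gene MAGEB2 (18.4-fold), KITLG, the KIT ligand gene (16.7-fold), EEF1A2 (13.8-fold), MALL (11.8-fold), ANXA10 (10.5-fold) and the galanin gene GAL (10.2-fold). Most of these genes lay near the background in another line, such as FLG at 6.75 in HCT116 and 6.77 in MCF10A beside an array median of 6.92, so their folds are understated and their order is uncertain.

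Of 14270 genes, 7767 differed between HCT116 and KLE (4188 higher and 3579 lower in HCT116), 7520 between MCF10A and KLE (3854 higher and 3666 lower in MCF10A) and 5916 between HCT116 and MCF10A (3223 higher and 2693 lower in HCT116). Higher than both other lines were 2508 genes in KLE, 2170 in HCT116 and 1730 in MCF10A, and 2369, 1194 and 1162 were lower than both. Each line was read on arrays of its own, the KLE cells also carried a control hairpin, and replicate numbers did not pair the lines. The difference of A from B and C lies within the KLE shCTRL group too. Without shCTRL replicate 1 the counts against KLE were 8362 for HCT116 and 8187 for MCF10A. Whether part of the differences between lines has the same source as that of A was not tested.

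Interferon-stimulated genes were lower in both other lines than in KLE. In HCT116 34 of 40 were lower and 2 higher (34 and 2 adjusted over the list alone; median -1, camera adjusted p = 1.7e-12; adjusted p = 0.0063 with an estimated correlation), and in MCF10A 30 lower and 4 higher (31 and 4 adjusted over the list alone; median -0.80, camera adjusted p = 5.5e-09; adjusted p = 0.0099 with an estimated correlation). IFI27 differed from KLE by -3.91 and -3.93 and MX1 by -3.42 and -3.41. Mesenchymal genes were lower in HCT116 than in KLE, 21 of 26 with 1 higher, also adjusted over the list alone (median -1.40, camera adjusted p = 5.6e-10; adjusted p = 0.0063 with an estimated correlation), with the cadherin gene CDH2 at -5.38, the intermediate filament gene VIM at -5.12 and the connective tissue growth factor gene CCN2 at -5.62. In MCF10A VIM differed by -0.18 from KLE and the list missed the threshold (camera adjusted p = 0.056). The Mullerian list was lower in MCF10A, 10 of 14, also adjusted over the list alone (camera adjusted p = 0.00022, and 0.027 with an estimated correlation, 0.077 with the replicate number as a block), and in HCT116, 9 of 14 (camera adjusted p = 0.0064, and 0.076 with an estimated correlation), with WFDC2 at -4.27 and PAX8 at -1.86 in HCT116. At an unadjusted limma p under 0.05, 2 of its genes were higher in MCF10A than in KLE and 3 in HCT116.

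The basal epithelium list was the largest shift of MCF10A, with 16 of 17 higher than in KLE, also adjusted over the list alone (median 2.90, camera adjusted p = 6.7e-12; adjusted p = 0.0051 with an estimated correlation), among them the basal keratin genes KRT5 (4.61) and KRT14 (3.89), and all 17 lower in HCT116 than in MCF10A. Among p53 targets 18 of 28 were higher in MCF10A than in KLE, also adjusted over the list alone (camera adjusted p = 9e-05, and 0.02 with an estimated correlation, 0.063 with the block), with the cell cycle inhibitor genes CDKN1A at 3.91 and SFN at 3.22. At an unadjusted limma p under 0.05, 19 of these targets were higher and 2 lower. E2F targets were higher in HCT116, 29 of 38 against KLE (31 adjusted over the list alone; median 0.82, camera adjusted p = 6.5e-07; adjusted p = 0.22 with an estimated correlation) and 32 against MCF10A (33 adjusted over the list alone; camera adjusted p = 1.3e-09; adjusted p = 0.087 with an estimated correlation), with the replication licensing gene CDT1 at 2.67 and RRM2 at 2.16 against KLE. Mismatch repair genes were higher in HCT116 than in MCF10A, 11 of 21 with none lower (15 adjusted over the list alone; median 0.46, camera adjusted p = 0.00028; adjusted p = 0.025 with an estimated correlation, 0.059 with the block), led by the clamp loader gene RFC5 (1.71) and the single-strand binding protein gene RPA2 (1.03). Against KLE 11 were higher in HCT116 and 1 lower (camera adjusted p = 0.092). MSH3 was read here by its bright probe. On its dim probe the log2 level was 7.28 in HCT116, 8.72 in KLE shCTRL and 8.54 in MCF10A. Cholesterol synthesis genes were lower in HCT116, 14 of 20 against KLE (14 adjusted over the list alone; camera adjusted p = 0.00087; adjusted p = 0.047 with an estimated correlation, 0.11 with the block) and 15 against MCF10A (16 adjusted over the list alone; camera adjusted p = 1.3e-06; adjusted p = 0.0082 with an estimated correlation).

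**Figure D5:**
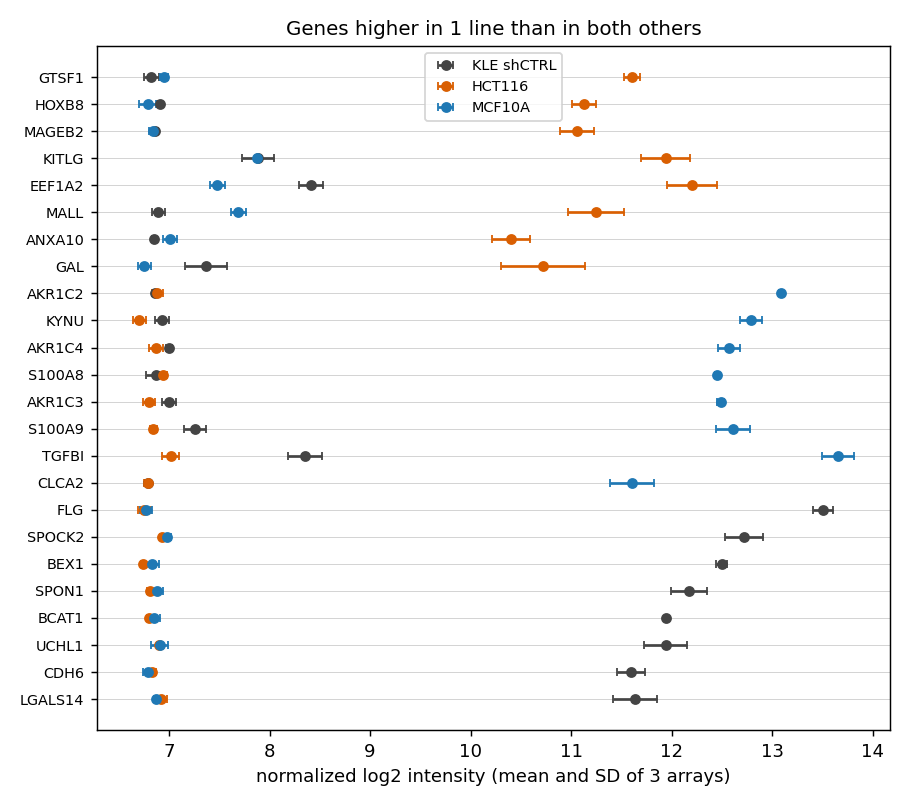
Normalized log2 intensity, as mean and SD of 3 arrays, of the 8 genes per line that set KLE, HCT116 and MCF10A apart. FLG is highest in KLE, AKR1C2 in MCF10A and GTSF1 in HCT116, with differences of 6.75, 6.21 and 4.66 to the nearer line.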

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

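The tests of noise in the shCTRL arrays, of the shCTRL culture, of the replicate letters, of hairpin delivery, of the targeted gene, of the depth of the knockdown and of single arrays were chosen only after the result was seen. The tests of the pooled GAGE signal and of the signs shared by 603 and 543, and the counts over other splits of the samples, were planned.

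These results stand out because effects under the same kind of contrast differed between targets or hairpins when the difference itself was tested. Between MSH3 and MSH6 hairpins 309 genes differed, and the interferon-stimulated list had a median difference of 0.59. In all 4 hairpin pairs MSH6 differed by 1.55, KLK6 by 1.18, CAMK2N1 by 0.78 and BTG3 by 0.60, the first of these being a target. Hairpins 059 and 062 differed in 21 genes and hairpins 543 and 603 in 176. Leaving out 062 replicate 1 gave 571 genes in place of 309 and 233 in place of 21, and leaving out 543 replicate 3 gave 81 in place of 176. CAMK2N1 lost its call in at least 1 pair without 059 replicate 2, 543 replicate 2 or 3, or 603 replicate 3. BTG3 lost its call on leaving out any of the 12 arrays but 603 replicate 2. MSH6 lost its call without any of the 059 arrays, without 062 replicate 2 or 3 or without 603 replicate 2 or 3. Over the 12 arrays left out, the differences stayed at 0.74 to 0.82 for CAMK2N1, 0.57 to 0.65 for BTG3 and 1.48 to 1.63 for MSH6. Probes that carry no gene, which the comparisons do not use, also changed. With both MSH3 hairpins 10 of 8951 passed, all lower, and with both MSH6 hairpins 11 passed, 1 higher and 10 lower. What these probes measure was not tested.

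The first pattern is the fall of the GAGE genes with all 4 hairpins. The lowest shCTRL array lay 1.27 above the highest knockdown array in mean log2 level (SD within groups 0.11). This gap decides nothing about noise in the control arrays. The genes averaged were those already called lower with all 4 hairpins on the same arrays. A state of the shCTRL culture alone is argued against for the further fall with 603, whose highest array lay 0.33 below the lowest of the other hairpins, although not for the fall they share. That the probes read near-identical transcripts as 1 pool is consistent with a median residual correlation of 0.647 between them, across arrays, where random sets of genes reached 0.23. Whether the common fall comes from the knockdowns or from the shCTRL culture cannot be told apart with 1 control group.

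The second pattern is the higher level of interferon-stimulated genes with MSH3 than with MSH6 hairpins. The replicate letter as the source is argued against by the smallest difference within a letter, 0.526 (highest 0.858, SD 0.18). A response to hairpin delivery as such was not testable, since every KLE group carries a hairpin, so the highest MSH6 array lying at -0.327 (SD 0.095) against shCTRL of the same letter decides nothing. On group means the smallest difference between targets exceeded the largest between hairpins of 1 target by 0.31 (0.54 against 0.229), but within letters, where 059 and 062 differ in opposite directions, this margin was only -0.00329 to 0.0116 (SD 0.0078). An effect of the targeted gene and off-target effects of single hairpins therefore cannot be told apart with 2 hairpins per target, and camera's call did not hold with an estimated correlation. Fry passed the list (adjusted p = 0.0023), but it rests on the same hairpins and does not separate these effects either.

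The third pattern is that hairpin 603 changed more genes than 543. A deeper fall of the target is argued against, since MSH6 was lower with 543 by -1.19 (SE 0.18). A single array is argued against, since the lowest count for 603 with 1 array left out, 152 without shCTRL replicate 3, exceeded the highest for 543, 48, by 104. A shared effect that is larger with 603 is consistent with 83.3% of its 323 genes having the same sign with 543, beside 63.5% on average and 69.6% at most in simulated unchanged groups that share the controls. The simulated noise was drawn for each gene independently, and genes that move together could widen the simulated range. How far 83.3% lies beyond unchanged groups is therefore not settled. A state of the shCTRL cells, which would also give shared signs, was not simulated and stays open, as do off-target effects of 603.

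Other splits of the samples were counted for each comparison. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In each the real split alone (1 split) gave as many genes. The real values were 59 for 059, 51 for 062, 48 for 543, 323 for 603, 176 between 543 and 603, 7767 for HCT116 against KLE, 7520 for MCF10A against KLE and 5916 for HCT116 against MCF10A, and the highest of the other splits was 0 for all of these by limma's adjusted p. Between 059 and 062 the real value was 21 and the highest other 9. For the combined results 100 splits were drawn. They treat arrays as independent, and the labels do not state separate cultures, so a chance difference between cultures is not excluded. The real split alone reached its 21 genes for both MSH3 hairpins (highest other 13, 1 of 100). Of these 21 genes 11 are GAGE genes, which may stand for 1 change. The real split also stood alone for MSH3 against MSH6 hairpins (309, highest other 9, 1 of 100) and for all 4 pairs (4, highest other 0, 1 of 100). Between targets the drawn splits, here and with letters kept, mix arrays of different hairpins. Any difference between single hairpins would then set the real split apart too. They do not decide whether the target matters, and regroupings of whole hairpins were not counted on their own. For both MSH6 hairpins (27 genes) 3 of 100 splits gave as many, and the highest other split gave 1507. That split took all A arrays as controls, so it points to the structure of the samples, and the blocked value of the real split was 97. Among 100 splits that keep 1 array of each letter in each group the highest others were 18 for MSH3 (1 of 100; a split that kept the real controls), 66 for MSH6 (4 of 100; a split with the 603 arrays as controls), 130 between targets (1 of 100; a split that kept the targets apart) and 1 for all 4 pairs (1 of 100). For the number of lists past camera's threshold chance was not excluded. It was 4 for MSH3 (26 of 100, highest other 6, and 54 of 100 with letters kept, highest other 7), 1 for MSH6 (87 and 88 of 100, highest other 5 in each) and 7 between targets (5 of 100, highest other 8, and 6 of 100 with letters kept, highest other 7).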

How the results depend on the processing

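The alternatives with normexp background correction, a batch term for A against B and C, arrays B and C alone and the GAGE genes counted as 1 gene were chosen after seeing the data, and all other tests here were fixed before. Where a value moved, the cause was not tested unless stated. Offsets of 1 and 50, quantile normalization within the arrays of a fit, no filter on dim probes and the mean of a gene's probes left every count within 1.5 times its main value and every target call as it was.

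Median scaling and values as deposited lowered the counts. The main counts were 59 for shMSH3 059 against shCTRL, 51 for shMSH3 062 against shCTRL, 48 for shMSH6 543 against shCTRL, 323 for shMSH6 603 against shCTRL, 21 for shMSH3, both hairpins, 27 for shMSH6, both hairpins, 309 for shMSH3 against shMSH6, 4 for shMSH3 against shMSH6, all 4 hairpin pairs, 21 for hairpin 059 against 062, 176 for hairpin 543 against 603 and 17 for the overlap of shMSH3 and shMSH6 changes. With median scaling they were, in that order, 19, 18, 17, 100, 11, 16, 31, 0, 11, 25 and 11, and with values as deposited 14, 10, 10, 50, 9, 10, 8, 0, 0, 1 and 9. At an unadjusted p under 0.05 limma still gave 24 higher and 8 lower in all 4 pairs with median scaling, 9 and 1 with values as deposited, and 6 higher and 510 lower between 059 and 062 with values as deposited. The fixed gene lists past camera's threshold were 12 in the main analysis, 20 with median scaling and 19 with values as deposited. For target transcripts: MSH6, shMSH6 543 against shCTRL, the change was -2.23 and -2.29, and for target transcripts: MSH6, shMSH6 603 against shCTRL, -1.24 and -1.36, none of which passed. Values as deposited gave 4740 for HCT116 against KLE shCTRL, 4053 for MCF10A against KLE shCTRL and 2920 for HCT116 against MCF10A. Cyclic loess gave 36 for hairpin 059 against 062 and 11 for the overlap of shMSH3 and shMSH6 changes, and normexp 38 for shMSH3 059 against shCTRL.

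Scaling also moved the balance of higher and lower genes. The main splits were 20 higher and 39 lower for 059, 24 and 27 for 062, 18 and 30 for 543, 108 and 215 for 603, 4 and 17 for both MSH3 hairpins, 5 and 22 for both MSH6 hairpins, 168 and 141 between targets, 4 and 0 for all 4 pairs, 4 and 17 between 059 and 062 and 126 and 50 between 543 and 603. With median scaling they were 0 and 19, 5 and 13, 1 and 16, 3 and 97, 0 and 11, 0 and 16, 27 and 4, 0 and 0, 0 and 11, and 25 and 0. With values as deposited they were 0 and 14, 1 and 9, 0 and 10, 0 and 50, 0 and 9, 0 and 10, 8 and 0, 0 and 0, 0 and 0, and 1 and 0. Cyclic loess gave 9 and 32 for 059, 7 and 25 for 543, 1 and 20 for both MSH6 hairpins, 154 and 79 between targets and 4 and 1 for all 4 pairs. Normexp gave 8 and 30 for 059, 11 and 24 for 062, 8 and 25 for 543, 1 and 14 for both MSH3 hairpins and 144 and 62 between targets. The median of all genes itself moved, by -0.13 for 059 with median scaling, and with values as deposited by -0.29 for 059, -0.21 for 603, -0.19 between 059 and 062, 0.11 between 543 and 603, -0.19 for the mean of the MSH3 hairpins and -0.15 for that of the MSH6 hairpins, so rises are judged against that shift.

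For lists, the sign of 4 values reversed, 3 of them with scalings that shift all genes. The mesenchymal and TGF-beta list, mean MSH3, had a median of -0.043 with median scaling and -0.147 with values as deposited, in both cases above the median of all genes (-0.082 and -0.19). The interferon-stimulated list, mean MSH3, was at -0.000618 with values as deposited, also above the median of all genes (-0.19), and the oxidative phosphorylation list, shMSH3 against shMSH6, at -0.00563 on arrays B and C alone. None of the 12 calls of the fixed gene lists held with an estimated correlation (0), and fry passed 4 lists, 3 of them among the 12. Over the other settings 185 list values kept direction and call and 27 weakened.

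In the order of shMSH3 059 against shCTRL, shMSH3 062 against shCTRL, shMSH6 543 against shCTRL, shMSH6 603 against shCTRL, shMSH3, both hairpins, shMSH6, both hairpins, shMSH3 against shMSH6, shMSH3 against shMSH6, all 4 hairpin pairs, hairpin 059 against 062, and hairpin 543 against 603, all 21 arrays in 1 fit gave 127, 109, 87, 538, 33, 48, 502, 14, 105 and 330, with more degrees of freedom. Only the groups compared gave 17, 16, 16, 157, 10, 11, 168, 0, 0 and 48, with fewer, 6 for the overlap of shMSH3 and shMSH6 changes, and no call for MSH6 with 603 at -0.93. In those fits limma gave 64 higher and 55 lower for all 4 pairs and 382 higher and 450 lower between 059 and 062 at an unadjusted p under 0.05. Array weights gave 711, 1635, 527, 1532, 308, 295, 1507, 70, 753 and 698, and 94 for the overlap. A stricter filter gave 34 for 059 and 10 between 059 and 062, and a variance trend with a robust prior 39 for 059 and 188 between targets. A minimum of 1.5-fold gave by construction fewer genes, 30, 31, 31 and 156 for the single hairpins, 79 between targets, 11 between 059 and 062 and 93 between 543 and 603, and 4121 for HCT116 against KLE shCTRL, 3862 for MCF10A against KLE shCTRL and 2895 for HCT116 against MCF10A. The mean of both hairpins gave 51 for MSH3 and 139 for MSH6, and the GAGE genes counted as 1 gene gave 11 and 17.

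The residuals set the KLE arrays of A apart from B and C and do not tell B from C. A block for the replicate letter gave, in the order of shMSH3 059 against shCTRL, shMSH3 062 against shCTRL, shMSH6 543 against shCTRL, shMSH6 603 against shCTRL, shMSH3, both hairpins, shMSH6, both hairpins, shMSH3 against shMSH6, shMSH3 against shMSH6, all 4 hairpin pairs, hairpin 059 against 062, and hairpin 543 against 603, 215, 193, 157, 1017, 51, 97, 1323, 42, 224 and 542 genes. All genes of the main counts for KLE passed in it too. It lowers the residual SD of the median gene from 0.127 to 0.0977 while the fold changes stay as they are. A batch term for A against B and C gave 264, 287, 194, 1127, 69, 117, 1496, 63, 278 and 608, and 31 for the overlap of shMSH3 and shMSH6 changes. Arrays B and C alone gave 1705, 2427, 754, 2443, 747, 491, 2437, 199, 1932 and 1198, and 170 for the overlap, with a residual SD of 0.0794. If B and C are closer than separate cultures would be, the last counts are too high, and the labels do not settle this. Beside the counts and members given, the block moved the adjusted p of the MSH3 dim probe with 062 from 0.062 to 0.026 and brought camera's adjusted p for antigen presentation with the MSH3 hairpins from 0.13 to 0.049. Between 543 and 603 it brought G2 and mitosis from 0.068 to 0.016, interferon from 0.068 to 0.045 and antigen presentation from 0.066 to 0.042. Between 059 and 062 it took the unfolded protein response from 0.029 to 0.057. Against shCTRL it moved the E2F list (0.077 to 0.042) and the mesenchymal list (0.046 to 0.11) with 062, the Mullerian list with 543 (0.12 to 0.049) and the cholesterol (0.073 to 0.028) and ribosomal lists (0.093 to 0.049) with 603. None of the gained calls held with an estimated correlation. It changed no other call of a list in KLE, and none of the report's calls of genes as changed was lost. In the lines, where numbers do not pair arrays, the block gave 7404, 7106 and 5534 genes, and it moved 1 camera call, end joining in HCT116 against KLE, from 0.046 to 0.053. With an estimated correlation 5 more were lost, p53 (0.02 to 0.063) and Mullerian (0.027 to 0.077) in MCF10A against KLE, cholesterol in HCT116 against KLE (0.047 to 0.11), and mismatch repair (0.025 to 0.059) and p53 (0.025 to 0.062) in HCT116 against MCF10A.

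Leaving out each array in turn gave these ranges. For shMSH3 059 against shCTRL the count was 18 to 64 (18 without 059 replicate 2, 19 without 059 replicate 3, and 38, 23 and 21 without shCTRL replicates 1, 2 and 3). For shMSH3 062 against shCTRL it was 21 to 273 (273, 22 and 21 without 062 replicates 1, 2 and 3, and 23 without shCTRL replicate 2 or 3). For shMSH6 543 against shCTRL it was 20 to 47 (29, 26 and 23 without 543 replicates 1, 2 and 3, 24 and 20 without shCTRL replicates 2 and 3). For shMSH6 603 against shCTRL it was 152 to 244 (159 without 603 replicate 3, 159 and 152 without shCTRL replicates 2 and 3). For shMSH3, both hairpins, it was 13 to 39 (13 without shCTRL replicate 2 or 3 or 059 replicate 2, 39 without 062 replicate 1). For shMSH6, both hairpins, it was 14 to 29 (16 and 14 without shCTRL replicates 2 and 3, 15 without 543 replicate 2 or 3). For the overlap of shMSH3 and shMSH6 changes it was 10 to 22 (11 and 10 without shCTRL replicates 2 and 3, 11 without 059 replicate 2 or 543 replicate 2 or 3). For shMSH3 against shMSH6 it was 146 to 571 (151 without 059 replicate 3, 571, 163 and 147 without 062 replicates 1, 2 and 3, 174 and 166 without 543 replicates 2 and 3, 146 without 603 replicate 3). For shMSH3 against shMSH6, all 4 hairpin pairs, it was 1 to 22 (1 without 059 replicate 2 or 603 replicate 3, 2 without 059 replicate 3, 062 replicate 2 or 3 or 543 replicate 2 or 3, 22 without 062 replicate 1). For hairpin 059 against 062 it was 6 to 233 (7 and 6 without 059 replicates 2 and 3, 233, 7 and 7 without 062 replicates 1, 2 and 3). For hairpin 543 against 603 it was 81 to 128 (94 and 81 without 543 replicates 2 and 3, 104 and 92 without 603 replicates 2 and 3). Fewer arrays leave fewer degrees of freedom, and the cause of the rise without 062 replicate 1 was not tested.

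For the lines the same ranges were 6946 to 8362 for HCT116 against KLE shCTRL, 6488 to 8187 for MCF10A against KLE shCTRL and 5060 to 5491 for HCT116 against MCF10A. For the fixed gene lists it was 9 to 16. Lists that lost camera's call were G2 and mitosis, mean MSH3, without shCTRL replicate 1 (-0.023) or 062 replicate 2 (-0.0964), and between targets G2 and mitosis without 543 replicate 1 or 603 replicate 2 (-0.0637), oxidative phosphorylation without 062 replicate 2 (0.116), 543 replicate 1 (0.0541) or 603 replicate 1 (0.0635), and ribosomal proteins without 543 replicate 1 (0.0396) or 603 replicate 1 (0.0464). The antigen presentation median between targets fell to 0.0995 without 062 replicate 2 and kept its call. For target transcripts: MSH3, shMSH3 059 against shCTRL, the change was -0.83 to -0.75, for MSH3 with 062 -0.76 to -0.49, for MSH6 with 543 -2.28 to -1.96 and for MSH6 with 603 -1.08 to -0.77.

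Of the named genes, the 9 GAGE genes left in this test (GAGE7 and GAGE12E were not part of it), LUM with the MSH3 hairpins and KLK6 kept their call whichever array was left out, as did all genes that set the lines apart. Without shCTRL replicate 2 or 3 a hairpin's call was lost for ATG4B, C6orf120, COL3A1 and KISS1 with MSH3 hairpins and for SULF1, LUM, PSMC4, ATG4B and C6orf120 with MSH6 hairpins. Their mean changes stayed at 0.61 to 0.68, 0.44 to 0.54, 0.94 to 1.09 and -1.02 to -0.77 for the first 4, and at 1 to 1.17, 0.97 to 1.16, 0.66 to 0.79, 0.65 to 0.73 and 0.40 to 0.50 for the others, over all arrays left out. Calls of these genes were also lost without single arrays of the hairpins, so that in all PSMC4 lost its call without 8 of 9 arrays, and KISS1 and COL3A1 with MSH3 hairpins and SULF1 and LUM with MSH6 hairpins without 6 of 9. Over all named genes 454 values kept direction and call with 1 array left out and 71 weakened, and 871 did so under other settings and 83 weakened. Fits of only the groups compared weakened 16, and median scaling and values as deposited 15 each.

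Signal over background limits what can be seen. With array medians from 87.71 to 122.2 above minima of 66.27 to 89.47, genes near the median are mostly background, and their folds are understated. Normexp correction moved the level of MSH6 with 543 from 23% to 19% of control and that of MSH3 with 059 on its dim probe from 57.9% to 47.4%.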

Other observations

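All observations in this part were described after the data were seen, and the tests of A against B and C were chosen only after that result was seen.

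KLE arrays of replicate A differed from B and C in many transcripts. Among the largest falls in A, PTMS, the parathymosin gene, differed from B and C by -2.68 (adjusted p = 2e-12), SNAR-A1, a small noncoding RNA, -2.59, the adhesion molecule gene L1CAM -2.52, the kinase gene DYRK1B -2.52, the atrophin gene ATN1 -2.52 and the growth factor gene MDK -2.11. The interferon regulatory factor gene IRF1 was higher by 2.08 (adjusted p = 1.5e-09) and the protease gene CAPN1 by 1.84. Among the fixed lists, 19 of 32 oxidative phosphorylation genes were lower in A and 4 higher (median -0.31, camera adjusted p = 0.0078; adjusted p = 0.92 with an estimated correlation), and 8 of 18 antigen presentation genes were lower and 2 higher (median -0.19, camera adjusted p = 0.0093; adjusted p = 0.92 with an estimated correlation). Of the G2 and mitosis list 18 of 35 were higher in A and 7 lower, and of the E2F list 17 of 37 higher and 4 lower, both without passing camera (adjusted p = 0.32 and 0.14). The A array of KLE shCTRL correlated across genes, which are not independent replicates, with HCT116 at 0.86 and with MCF10A at 0.859, against 0.834 and 0.829 for B and 0.835 and 0.829 for C. What sets A apart is not stated in the labels and was not tested further.

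Expression of the GAGE genes in KLE with hairpin 603 lay at the level of the other lines. Their mean log2 level was 6.847 to 6.866 on the 603 arrays, 6.825 to 6.84 in HCT116 and 6.84 to 6.873 in MCF10A, close to the array median of 6.92 and hence to background, against 8.812 to 9.019 with shCTRL. With 059 it was 7.392 to 7.5, with 062 7.245 to 7.399 and with 543 7.198 to 7.545.

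Among other cancer/testis genes, VCX3A, VCX3B and VCX rose with 062, by 1.74, 1.70 and 1.67, and did not pass with 059 (0.31, 0.32 and 0.27), 543 (0.52, 0.55 and 0.52) or 603 (-0.57, -0.61 and -0.58), although with the block they were lower with 603 (adjusted p = 0.037, 0.012 and 0.013). PAGE5 (log2 0.87) and the export factor gene NXF2 (1.02) also rose with 062, and MAGEC1 rose with 603 (1.06, adjusted p = 7.8e-05). Whether these differences have a common source was not tested.

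In the control lines further lists differed. NF-kB and cytokine genes were lower in HCT116 than in MCF10A, 13 of 21 with none higher, also adjusted over the list alone (median -0.59, camera adjusted p = 1.8e-06; adjusted p = 0.0082 with an estimated correlation), and mesenchymal genes 14 of 26 with none higher (median -0.83, camera adjusted p = 7.4e-08; adjusted p = 0.0082 with an estimated correlation). G2 and mitosis genes were higher in HCT116 than in MCF10A, 22 of 35 (camera adjusted p = 2.6e-05; adjusted p = 0.23 with an estimated correlation). p53 targets were lower in HCT116 than in MCF10A, 15 of 28 (camera adjusted p = 0.00089, and 0.025 with an estimated correlation, 0.062 with the replicate number as a block). At an unadjusted limma p under 0.05, 4 of them were higher and 16 lower.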
